A study of Mus musculus with 24 samples.

How the data were processed

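Total RNA was isolated from pools of 15 frozen expanded mouse blastocysts (20 in HC6), per the labels' protocols. From each pool 2 ng of total RNA was amplified and labelled with the dye Cy3, and each pool was hybridised to its own one-colour Agilent array. The 24 pools fall into 6 conditions known by code only, with 4 pools each, and the labels number the pools of a condition from 1 to 4.

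The deposited scanner files hold spot intensity values on a linear scale, made with Agilent Feature Extraction 10.10.1.1 per the file headers and the submitters' processing notes. Per the file headers, the processed intensity is background subtracted and detrended within the array, and low values are replaced by a surrogate; it is not normalized between arrays. The mean and background intensity columns are as measured, per the file headers. The other deposited columns used are flags for spots well above background, saturated or outlying. The submitters' processing notes also name limma, with no version. The series also has the authors' deposited table of log2 values for 27101 probes, which was compared with the scanner signals. Each of its 24 columns correlated best with its own array in deviations from probe means (r across probes from 0.834 to 0.888), its column medians were between 7.00 and 7.01, and 443 values were missing. Its values are therefore read as log2 values put on a common scale between arrays. How its probes were chosen, its background treatment and its exact normalization are not given in the sources used here.

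For the main values, control spots and spots marked as outliers were left out, the log2 of the processed signal was averaged over spots of one probe, and the 75th percentile of each array was subtracted. The arrays hold 56605 probes on 59305 spots that are not controls. Saturation was recorded on 0 spots of any array. A probe was kept if it was well above background on at least 4 of 24 arrays and had at least 2 values in each condition, and a gene was represented by its brightest kept probe. Of the probes, 27144 passed the background filter, and 18448 genes were tested, counting as genes also features with no symbol. Gene names of 41700 probes were found as symbols in the reference gene table, 1518 more were named through their accession and 520 through a unique synonym, and 12867 kept the name in the file. Of the genes on the lists, 6 were not found on the array by name.

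One linear model with the 6 condition means was fitted with limma 3.58.1 in R 4.3.3, with moderated tests from eBayes and Benjamini-Hochberg adjustment at 0.05. Files were read with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and the R package data.table (version 1.17.8), and figures drawn with matplotlib 3.10.9. The moderated F-test asked for any difference among conditions. Because no control is named, each condition was set against the mean of the other 5, adjusted within a condition, and all 15 pairs were tested with adjustment over genes and pairs together. Camera with a preset correlation of 0.01 tested 32 gene lists in each condition against the other 5, adjusted over all 192 tests, on genes without a missing value and lists with at least 3 such genes. The lists cover embryo lineages, estrogen receptors and targets, stress and metabolic pathways, other cell types and sex-linked genes. A list score was the mean, over a list's genes, of the deviation from the 24-array mean; its exact permutation test used all 10626 choices of 4 pools.

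The design, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. The rule names the 25 genes of smallest p in the F-test among calls. For each condition it names the 5 highest and 5 lowest calls, or, where none passes, the 2 of smallest p as values. For pairs it names the 5 highest and 5 lowest calls of the 3 pairs with most calls. In a described list it names up to 4 members of smallest p. It always names Esr1, Esr2, Gper1, Nanog, Pou5f1, Cdx2, Gata6, Xist and the Y-linked genes. Features known only by an accession, a probe, a Gm number or a Rik clone, and near-identical multigene families, are counted and not named. Genes outside the rule are said to be so where they appear; those that passed over a list alone in lists without a call were named after their values were seen.

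The same code was tested on simulated arrays drawn from the real genes' means and spreads, with 50 genes changed in HC1 at each of 4 fold sizes. Each gene was drawn on its own, with no array position effect and no correlation between genes, so the check does not cover these. With no gene changed, 0 genes were called. With these changes, 5 unchanged genes were called in HC1 and 6 by the F-test, of 18448.

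Alternatives were normexp background correction (offset 50) with quantile normalization, quantile normalization of the processed signal, a percentile over probes detected on all arrays, the authors' table, other filters and probe rules, slide as a fixed or random block, fits within each slide, the replicate number as a block, array weights, trended and robust eBayes, the mean of the Y-linked genes as a covariate, leaving out each array, and other set tests. Blocks for slide row and array position, fits within each row, and a fit without HC6 replicate 3 and HC5 replicate 4 were added after seeing the data. The 3 slides were each scanned once with 8 arrays in 2 rows, and every slide and row held all 6 conditions. Arrays of one condition correlated at 0.963 to 0.988 across genes, and no pair of arrays had identical values.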

Results

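RNA from pools of mouse blastocysts, embryos at the last stage before implantation, was profiled on 24 one-colour microarrays. The samples carried 6 condition codes, HC1 to HC6, with 4 pools per code. A pool held 15 frozen expanded blastocysts, or 20 in HC6, so no HC6 contrast can separate the code from pool size. The title of the series concerns bisphenol A, a plastic monomer that can act on estrogen receptors, and activation of membrane estrogen receptors. The labels do not say which treatment each code stands for or which code is the control, so the 6 codes were compared with one another. Between 38.6% and 49.7% of spots were well above background on each array, and the 75th percentile of the processed signal ran from 65.9 in HC5 replicate 4 to 181 in HC3 replicate 3. After filtering, 18448 genes were tested. The number of arrays limits the precision. No label says that the pools of one code came from separate animals, so the p-values measure the spread between pools.

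Of the genes for the 3 main estrogen receptors, only that for estrogen receptor beta had a probe well above background on every array. Esr1, which encodes estrogen receptor alpha, had 7 probes, none of which was well above background on more than 2 of 24 arrays. The single probe for Gper1, the G protein-coupled estrogen receptor, was well above background on 0 of 24 arrays. One of the probes for Esr2, which encodes estrogen receptor beta, was well above background on 24 of 24 arrays with a normalized log2 signal of 2.52 ± 0.13 (SD, n = 24), while the other Esr2 probe reached that level on 1 of 24 arrays, so the probes of this gene disagree. The mean of the first Esr2 probe lay between 2.45 ± 0.14 in HC2 and 2.55 ± 0.12 in HC6 (log2, SD, n = 4 each). The limma F-test over the 6 conditions gave an adjusted p of 1 for Esr2. The genes of the estrogen receptor list that were tested numbered 14 of 18 on the array, and the list's smallest adjusted p in any condition was 0.551. The classical estrogen target list, with 13 of 22 genes tested, had a smallest adjusted p of 0.368.

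The first comparison asked whether any gene differed among the 6 conditions. The lineage genes of the blastocyst were bright in all of them. Pou5f1, a pluripotency factor of the inner cell mass, had a normalized log2 signal of 3.63 ± 0.25 over the 24 pools (SD). Nanog, a factor of the epiblast, stood at 1.11 ± 0.32. Cdx2, a factor of the trophectoderm, stood at 5.32 ± 0.27, and Gata6, a factor of the primitive endoderm, at 4.95 ± 0.18. The adjusted p of the limma F-test was 1 for each of these 4 genes. In single contrasts with the other conditions, the 95% interval of the Cdx2 difference ran from -0.46 to 0.19 log2 in HC3 and from -0.22 to 0.43 in HC5. Without HC5 replicate 4, the pool of highest Cdx2 (6.13), the HC5 difference turned from 0.10 to -0.14, and without HC3 replicate 2 the HC3 difference was -0.03 in place of -0.14. The Pou5f1 interval ran from -0.46 to 0.14 in HC1, and without HC1 replicate 1 the difference was -0.04 in place of -0.16. Gata6 in HC5 had a mean of 4.73 ± 0.28 against 5 in the other 20 pools, with an interval of -0.46 to -0.06 and an adjusted p of 0.875. Without HC5 replicate 4, the pool of lowest Gata6 (4.36), the difference was -0.14 in place of -0.26, with an interval of -0.33 to 0.05. Xist, the RNA that silences one X chromosome in female embryos, spanned a 6.92-fold range between pools. Of the Y-linked genes, Uty spanned a 13.4-fold range, Ddx3y a 9.19-fold range, Eif2s3y a 4.2-fold range and Kdm5d a 3.01-fold range. The probes used were well above background on 17 of 24 arrays for Uty, 16 for Ddx3y and 19 for Kdm5d, so the low ends of these 3 ranges lie at background and the folds are not exact. None of these 5 genes passed the F-test (adjusted p = 1 each).

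**Figure D1:**
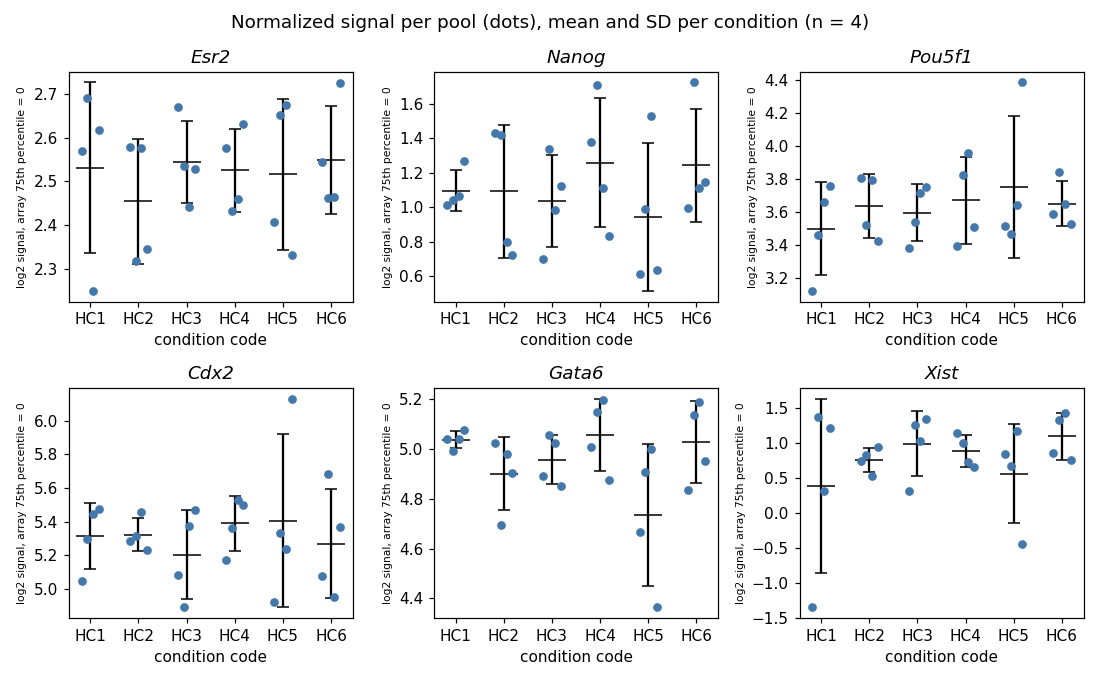
Normalized log2 signal (y axis, array 75th percentile set to 0) of Esr2, Nanog, Pou5f1, Cdx2, Gata6 and Xist in each of the 6 condition codes (x axis). Dots are pools, and bars give the mean and SD (n = 4). No gene shown passed the F-test, and the lowest Xist pool stands at -1.35 in HC1.

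Across all genes, the limma F-test with Benjamini-Hochberg adjustment called 0 of 18448 genes. At an unadjusted p under 0.05 it gave 387 genes, where 922 would be expected by chance. In simulated arrays with the real genes' means and spreads, in which 50 genes per size were changed in HC1 alone, the F-test over 18448 genes recovered 44% of genes changed 2-fold and 94% of genes changed 4-fold.

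The second comparison set each condition against the mean of the other 5. No gene passed in any of the 6 conditions, so the 2 named genes of smallest p in each are given as values. In HC1, Irx3os, a noncoding RNA beside Irx3, stood at -1.35 ± 0.97 against -2.60 ± 0.36 in the other 20 pools (log2, SD, n = 4 and 20), with an adjusted p of 0.484. It was well above background on 3 of 4 HC1 arrays and 6 of 20 others, it was higher in 3 of 4 pools, and leaving out HC1 replicate 3 gave an adjusted p of 7.41e-05. Over the alternatives its adjusted p ran from 7.41e-05 to 1, and within slide 2 its difference was -0.155. Pla2g12a, a secreted phospholipase A2, stood at 0.72 ± 0.09 in HC1 against 1.11 ± 0.12, with adjusted p = 0.484. In HC2, the small nucleolar RNA Snora78 was 0.81 log2 above the others in 4 of 4 pools, with adjusted p = 0.754. Nsg2 was 3.18 log2 above them in HC2, with an SD of 3 log2 between the 4 pools and an adjusted p of 0.754. Its probe was well above background on 2 of 4 HC2 arrays and 2 of 20 others, so this difference is one against background and not exact. Without HC2 replicate 1 its adjusted p was 0.0317, and over the alternatives it ran from 0.0317 to 1. In HC3, Kcnk16, a potassium channel gene, was well above background on 0 of 4 arrays against 9 of 20 others, with adjusted p = 1. With the dim HC3 values raised to a background floor it was 1.37-fold lower. Without HC3 replicate 1 its fitted difference was -0.544 log2 in place of -1.07. The floor is, per array, the higher of the lowest signal among probes well above background and the dim probe's own signal. The 1.37-fold value is not a lower bound. Most of the other 20 arrays were also not well above background, and the spread between pools does not enter it. Wnk4, a kinase gene, was 1.02 log2 higher in HC3, with adjusted p = 1, and its probe was well above background on 3 of 4 HC3 arrays and 4 of 20 others. The Wnk4 difference was -0.126 log2 after normexp and quantile normalization and 0.41 with the mean of the gene's probes. The brightest probe was chosen anew under each normalization, so a gene's probe could differ between such values. The authors' values had slopes of 0.759 to 0.794 on the log2 processed signal, so sizes there are not on the same scale. In HC4, Fam167b stood at -1.33 ± 2.49 against -4.38 ± 0.82, with adjusted p = 0.998; the adjusted p was 0.0126 with array weights and 0.000441 without HC4 replicate 4, and over the alternatives it ran from 0.000441 to 1. Its probe was well above background on 3 of 4 HC4 arrays and 2 of 20 others, so the size is not exact, and within slide row 2 the difference was -0.415. Strip2 in HC4 was at -0.63 log2 relative to the others, with adjusted p = 0.998. In HC5, Klhl1 was 0.76 log2 above the others, with adjusted p = 0.837, and Fmr1, which encodes the fragile X RNA-binding protein, was at -0.43 log2, with adjusted p = 0.837. In HC6, Fam131a was at -1.36 log2, with adjusted p = 0.273. Foxa3, a forkhead transcription factor gene of endoderm, was at -1.04 log2 in HC6, with adjusted p = 0.723. The Fam131a and Foxa3 probes were each well above background on 1 of 4 HC6 arrays and 12 of 20 others. The differences of Irx3os, Wnk4, Fam131a and Foxa3 thus also rest on background signals and are not exact. After normexp and quantile normalization the log2 differences were 0.372 for Irx3os, 0.387 for Snora78, 1.095 for Nsg2, -0.148 for Kcnk16, 0.899 for Fam167b, -0.171 for Strip2, 0.349 for Klhl1, -0.129 for Fmr1, -0.21 for Fam131a and -0.177 for Foxa3. In the authors' deposited values they were 0.557 for Irx3os, 0.468 for Snora78, 1.236 for Nsg2, -0.294 for Kcnk16, 0.312 for Wnk4, -0.31 for Strip2, 0.426 for Klhl1, -0.166 for Fmr1, -0.289 for Fam131a and -0.236 for Foxa3.

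Some of the probes behind these values are placed here on mm9, the build named in the array's annotation. The Irx3os probe lies on chromosome 8 from 94329643 to 94329702, and that of Pla2g12a on chromosome 3 from 129597769 to 129597828. The Snora78 probe lies on chromosome 17 from 24856697 to 24856756, the Klhl1 probe on chromosome 14 from 96505534 to 96505593 and the Fmr1 probe on chromosome X from 65948200 to 65948259. The Fam131a probe lies on chromosome 16 from 20703004 to 20703063 and the Foxa3 probe on chromosome 7 from 19599053 to 19599112.

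The count of genes called by limma was 0 in each of the 6 contrasts. At an unadjusted p under 0.05 there were 590 genes in HC1, 415 in HC2, 292 in HC3, 349 in HC4, 1012 in HC5 and 545 in HC6, against 922 expected by chance. The median standard error of a contrast was 0.151 log2. The 95% interval lay within a 2-fold change in either direction for between 85.5% of genes in HC5 and 87.6% in HC3. In the simulated arrays, with changes in HC1 alone among 18448 genes, this contrast recovered 46% of genes changed 1.5-fold. It recovered 62% of genes changed 2-fold and 96% of genes changed 4-fold, with the same limit on what was simulated.

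The third comparison took all 15 pairs of conditions in one family. No gene and pair combination passed in the limma fit, and 7867 combinations had an unadjusted p under 0.05, where 13836 would be expected by chance. The fewest such genes, 286, were found between HC3 and HC4, and the most, 860, between HC1 and HC5. The smallest single p was 5.4e-06, between HC4 and HC6. The 95% interval lay within a 2-fold change for between 76.7% and 79.6% of genes in a pair.

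The fourth comparison asked whether genes of 32 lists, fixed before the data were examined, were shifted together in one condition relative to all other genes. With camera and its preset correlation of 0.01, 8 of 192 list and condition tests passed, in 4 lists. With the correlation estimated from the data, 0 of 192 passed and the smallest adjusted p was 0.653. No gene of any list passed when adjusted over all genes, and the counts adjusted over the list alone are given with each list.

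Genes of cholesterol synthesis were called as shifted upward in HC5 with the preset correlation. Of 20 measured members, 19 were higher in HC5 than in the other conditions, with a median of 0.21 log2 and an adjusted p of 1.01e-07 with the preset correlation (adjusted p = 0.987 with an estimated correlation). Adjusted over the list alone, 4 genes passed, and over all genes 0. Cyp51, the lanosterol demethylase, stood at 2.68 ± 0.24 in HC5 against 2.21 ± 0.21 in the other 20 pools. Mvd stood at 1.41 ± 0.50 against 0.92 ± 0.19, and Fdps, the farnesyl diphosphate synthase, at 5.43 ± 0.24 against 5.09 ± 0.19. The list score, the mean deviation of its members from their 24-array means, was between 0.06 and 0.33 in the 4 HC5 pools, and an exact two-sided permutation test of that score gave p = 0.0168 (adjusted over 192 tests, 0.989). The adjusted p of the HC5 shift ran from 4.91e-12 to 0.987 over the alternatives. With slide as a block and the preset correlation the HC5 median was 0.224 (adjusted p = 7.08e-07). It was 0.193 within slide 1, 0.279 within slide 2 and 0.184 within slide 3. Slides 1 and 2 held 1 HC5 pool each, so those values do not show replication across slides. The same list was called as shifted downward in HC3 (camera adjusted p = 0.000326, and 0.987 with an estimated correlation). There 16 of 20 members were lower, with a median of -0.11 log2. The other conditions that HC3 was set against include HC5, so part of this difference mirrors the HC5 values. The HC3 call is thus not a separate result from the HC5 call. In HC2, 17 of 20 members were also lower, with a median of -0.11 log2, but the test did not pass (adjusted p = 0.0642). The difference between HC2 and HC3 was not tested. An exact two-sided permutation test of the HC3 score gave p = 0.255 (adjusted, 0.989). In HC3 the member of smallest p was Dhcr7, at 0.32 ± 0.12 against 0.57 ± 0.21, and 0 genes passed over the list alone. The HC3 shift had a median of -0.0743 and an adjusted p of 0.246 without HC3 replicate 1 and one from 5.87e-08 to 0.987 over the alternatives. With slide as a block its median was -0.121 (adjusted p = 0.000391) and within slide row 2 it was 0.0234 (adjusted p = 0.945). Within slide 2 the HC3 median was -0.0991. Within slides 1 and 3, with 1 HC3 pool each, it was -0.146 and -0.0872.

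Genes of the 2-cell stage are normally switched on at the first wave of transcription of the embryo. With the preset correlation they were called as shifted upward in HC6 and HC2 and downward in HC3 and HC4. Of 15 list genes on the array, 9 were tested and 8 had no missing value. In HC6, 8 of 8 members were higher, with a median of 2.12 log2 (adjusted p = 6.5e-08, and 0.653 with an estimated correlation), and 5 passed when adjusted over the list alone. In HC2, 8 of 8 members were higher, with a median of 1.30 (adjusted p = 6.22e-06, and 0.906 with an estimated correlation), and 1 passed over the list alone. In HC4, 7 of 8 were lower, with a median of -1.28 (adjusted p = 2e-05, and 0.906 with an estimated correlation). In HC3, 8 of 8 were lower, with a median of -1 (adjusted p = 0.000394, and 0.987 with an estimated correlation). In HC1, 6 of 8 were also lower, with a median of -0.76, but the test did not pass (adjusted p = 0.441). The list scores of the 4 HC5 pools lay between -0.69 and -0.22. In HC3 and HC4, Zscan4a, Zscan4b, Zscan4f and Usp17le, which fall outside the rule for named genes and were chosen after their values were seen, were well above background on 0 of 4 arrays and on 4 of 20 others, so the lower values there are background signals set against a mean raised by a few pools. The log2 sizes of this list are therefore not exact in any condition. Most members belong to near-identical multigene families, so single members are uncertain. The members also vary together between pools (estimated correlation 0.388), so counts of members higher, lower or passing do not count separate signals. Zfp352, the one member outside such families, stood at 1.03 ± 0.46 in HC6 against 1.01 ± 0.34 (SD, n = 4 and 20). Zscan4a, Zscan4b and Zscan4f were well above background on 2 of 4 HC6 arrays and 2 of 20 others, and the SD of Zscan4f between the 4 HC6 pools was 3.94 log2. The score in HC6 ran from -0.26 to 4.73, and leaving out HC6 replicate 3 moved the median of the shift from 2.12 to 0.86 (adjusted p = 0.0118). In that pool the trophectoderm score was -0.376 and the cumulus and granulosa score 0.759, the lowest and the highest of the 24 pools. An exact two-sided permutation test of the 2-cell score gave p = 0.0136 for HC6, 0.0676 for HC2, 0.0966 for HC4 and 0.17 for HC3 (adjusted, 0.989 each). With slide as a block the HC6 median was 2.09 (adjusted p = 1.23e-08). It was 0.171 within slide 1 and 2.22 within slide 3, with 1 HC6 pool each, and 3.14 within slide 2. For HC2 it was 1.34 with slide as a block (adjusted p = 4.37e-05) and 2.26 within slide 1. Within slides 2 and 3, with 1 HC2 pool each, it was -0.764 and 0.48. Within slide 2 the HC2 test and median differed in sign. For HC4 it was -1.16 with slide as a block (adjusted p = 3.7e-05) and -0.784 within slide 3. Within slides 1 and 2, with 1 HC4 pool each, it was -1.28 and -1.06. The HC4 shift had an adjusted p of 0.0721 in the authors' deposited table of values. For HC3 it was -1.06 with slide as a block (adjusted p = 0.00302) and -0.814 within slide 2. Within slides 1 and 3, with 1 HC3 pool each, it was -0.469 and -1.01. Without HC3 replicate 2 the HC3 median was -1.1 and its adjusted p 0.0616. Without HC2 replicate 1 the HC2 median was 0.657 (adjusted p = 0.0242). The HC6 call was lost within slide row 1, and the HC2, HC3 and HC4 calls were lost within slide row 2. Slide row 2 held 1 HC4 pool. After normexp and quantile normalization the medians were 0.757 in HC6, 0.225 in HC2, -0.303 in HC4 and -0.315 in HC3, and in the authors' deposited values they were 0.997, 0.497, -0.408 and -0.497. Over the alternatives the adjusted p ran from 7.9e-15 to 0.991 in HC6, from 2.11e-15 to 0.97 in HC2, from 5.38e-08 to 0.97 in HC4 and from 3.24e-06 to 0.987 in HC3.

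**Figure D2:**
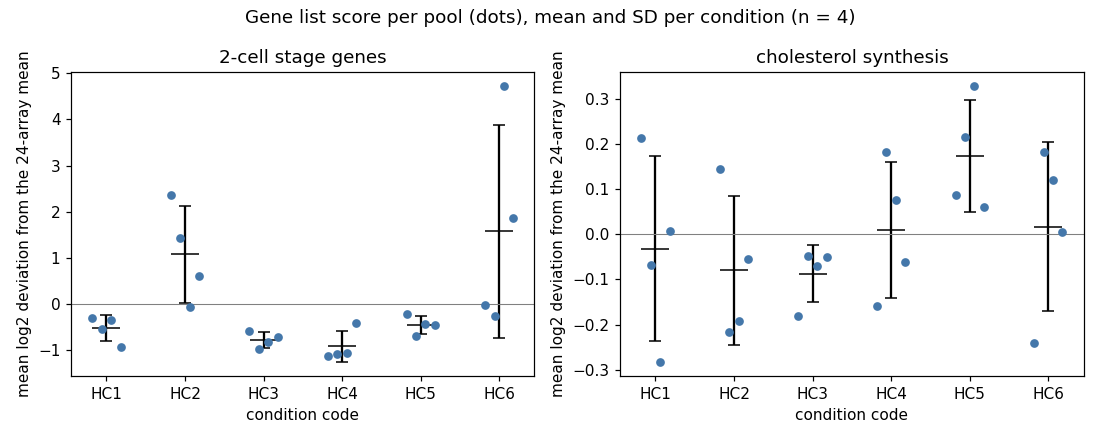
Mean log2 deviation from the 24-array mean (y axis) of the 2-cell stage genes and the cholesterol synthesis genes in each condition code (x axis). Dots are pools, and bars give the mean and SD (n = 4). HC6 replicate 3 stands at 4.73 in the left panel, and the 4 HC5 pools lie between 0.06 and 0.33 in the right panel.

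Primitive endoderm genes were called as shifted upward in HC1 with the preset correlation. Of 19 measured members, 19 were higher, with a median of 0.15 log2 (adjusted p = 0.00839, and 0.987 with an estimated correlation), and 0 passed over the list alone. In HC4, 19 of 19 members were also higher, with a median of 0.13 log2 and 4 of 4 pools in that direction, but the test did not pass (adjusted p = 0.211). The difference between HC1 and HC4 was not tested. Sox7, an endoderm transcription factor gene, stood at 0.90 ± 0.28 in HC1 against 0.53 ± 0.49, and Fn1, which encodes fibronectin, at 4.63 ± 0.09 against 4.47 ± 0.24. The median was 0.1 with slide as a block (adjusted p = 0.0765) and -0.166 within slide 1. Within slides 2 and 3, with 1 HC1 pool each, it was 0.325 and 0.191. Without HC1 replicate 1 the median was 0.057 (adjusted p = 0.422), and without HC1 replicate 3 it was 0.0529 (adjusted p = 0.29). The adjusted p without HC5 replicate 3 was 0.0537. Within slide row 2 it was 0.931, and with slide and slide row as blocks 0.0801. Without HC1 replicate 2 the median was 0.269, and over the alternatives the adjusted p ran from 1.31e-05 to 0.987. The score was higher in 3 of 4 HC1 pools, and its exact two-sided permutation test gave p = 0.302 (adjusted, 0.989).

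Heat shock genes were called as shifted downward in HC2 with the preset correlation. There 14 of 14 members were lower, with a median of -0.09 log2 (camera adjusted p = 0.0406, and 0.987 with an estimated correlation), and 0 passed over the list alone. Hspb1, a small heat shock protein gene, stood at 5.86 ± 0.15 in HC2 against 6.07 ± 0.19. In HC2, 3 of 4 arrays lay in slide row 2, where the list's median difference from row 1 was -0.16 log2 (adjusted p = 0.112). With slide row as a block the HC2 median was -0.0349 (adjusted p = 0.302), and with slide and slide row as blocks it was -0.0177 (adjusted p = 0.503). The median was -0.0716 with slide alone as a block (adjusted p = 0.135). It was 0.0464 within slide 1, where test and median differed in sign. Within slides 2 and 3, with 1 HC2 pool each, it was -0.316 and 0.0351. This call was lost in 12 of the 24 fits that left out an array, with a median of -0.0456 and an adjusted p of 0.493 without HC2 replicate 3, and also after normexp and quantile normalization (0.0564), with quantile normalization (0.0762) and in the authors' deposited table of values (0.218). Of the 48 alternatives, 29 lost the call with its direction kept and 1 lost it with its direction turned, and the adjusted p ran from 0.00216 to 0.996. The score was lower in 2 of 4 HC2 pools, and its exact two-sided permutation test gave p = 0.181 (adjusted, 0.989).

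No call was made in the other 28 lists, whose smallest adjusted p ran from 0.0642 to 0.716. The epiblast list, with 22 of 22 genes tested, had a smallest adjusted p of 0.214, and the trophectoderm list, with 18 of 20, one of 0.262. Among stress and damage responses the smallest adjusted p was 0.127 for p53 targets, 0.262 for apoptosis, 0.278 for NRF2 and antioxidant genes, 0.468 for the unfolded protein response and 0.615 for AhR and xenobiotic receptors. Among metabolic lists it was 0.293 for glycolysis, 0.297 for oxidative phosphorylation, 0.262 for lipid uptake and storage and 0.672 for steroid synthesis. It was 0.184 for DNA methylation and chromatin, 0.716 for imprinted genes, 0.468 for the cell cycle, 0.441 for junctions and cavitation, 0.468 for hatching and implantation, 0.428 for WNT and Hippo targets and 0.218 for interferon and antiviral genes. For markers of other cells it was 0.441 for oocytes, 0.668 for cumulus and granulosa cells, 0.262 for sperm and testis, 0.368 for oviduct and uterine epithelium and 0.568 for blood and immune cells. For the Y-linked list it was 0.297 and for X inactivation 0.441. The list of immediate early and ERK feedback genes had the 0.0642, in HC1. In that list 2 genes passed over the list alone, and 0 over all genes. Dusp1, a phosphatase gene of ERK feedback, stood at 1.72 ± 0.14 in HC1 against 2.09 ± 0.20, with adjusted p = 1 over all genes. Ier3 was not well above background on any of the 4 HC1 arrays and was so on 8 of 20 others. In HC1, 1 gene each also passed over the list alone in the glycolysis list (Slc16a3, a lactate transporter gene well above background on 1 of 4 HC1 arrays and 16 of 20 others) and in the WNT and Hippo list (Ccn1, a matricellular protein gene, at -0.48 log2), and both had an adjusted p of 1 over all genes.

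Array position moved with many genes. The first principal component held 19.1% of the variance. It lay between 22.66 and 51.76 on the 9 arrays in the second slide row and columns 2 to 4, and between -34.32 and -2.84 on the other 15. With condition in the model, 2267 genes differed between the slide rows at an adjusted p under 0.05. Of these, 1698 were lower in the second row and 569 higher. Between the 9 arrays and the other 15, 5192 genes differed by the same test. That split was read off the first component of the same data, so this count is not an independent test. Each slide and each row held all 6 conditions. With slide row, slide, or array position as a block, the F-test, the 6 contrasts and the pairs again gave 0 calls.

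**Figure D3:**
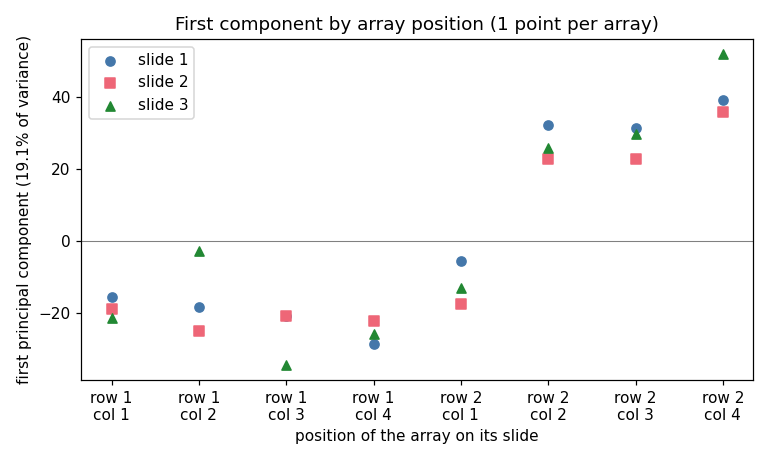
First principal component (y axis, arbitrary units, 19.1% of variance) of each of the 24 arrays by row and column on its slide (x axis), with 1 point per array and 1 marker per slide. The 9 arrays in row 2 and columns 2 to 4 lie at 22.66 or higher, on all 3 slides.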

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

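The tests of slide row against probe GC content, between probes of one gene and against other ways of assigning rows were set down before their results were seen; the other tests in this part were chosen after the result was seen. In 165 groups of 4 pools, 8 held a pool whose gap to the nearest pool took most of the group's range, and chance gives about 8, since it marks about 1 in 20 groups. For the 2-cell stage genes, HC4 replicate 4 stood at -0.406 in mean log2 deviation while the other HC4 pools lay between -1.12 and -1.06. For cholesterol synthesis, HC3 replicate 1 stood at -0.18 and the others between -0.07 and -0.048. For primitive endoderm genes, HC6 replicate 1 stood at 0.125 and the others between -0.221 and -0.162. For heat shock genes, HC5 replicate 4 stood at -0.422 with the others between 0.02 and 0.071, and HC6 replicate 1 at -0.533 with the others between 0.245 and 0.338. In normalized log2 signal, Kdm5d stood at -1.17 in HC2 replicate 2 (others -1.87 to -1.79), Irx3os at -3.31 in HC6 replicate 4 (others -2.39 to -2.34), and Snora78 at -0.694 in HC4 replicate 2 (others -1.14 to -1.07).

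Many genes differed between the slide rows. The count of 2267 genes came with condition in the model, which argues against unequal numbers of each condition in the rows, and only 1 of 100 ways of assigning rows within conditions, the real one, gave as many (highest other, 7 genes). The row difference rose with the GC content of the probe (Spearman rho = 0.417 across 18040 probes, which are not independent replicates), so probe chemistry at a slide position, or a labelling step that depends on GC, may contribute. The probes of one gene shared the row difference less than they shared the deviations of single arrays (ratio of correlations 0.662), and this value lies between the bounds set for differing RNA, so that explanation cannot be told apart. In the second row all 3 arrays of column 1 lay outside the range of the 9 others on the first component. This split was read off the same component, so it describes these arrays and does not test an effect of column.

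Many 2-cell stage genes were far above the other arrays in HC6 replicate 3. Zfp352 stood only 0.34 log2 above the median of the other arrays there, and Zscan4d was not well above background. The list score was less high in HC2 replicate 1 (2.36), HC6 replicate 4 (1.87) and HC2 replicate 2 (1.43). HC6 replicate 3 also had the lowest trophectoderm score (-0.376), the highest cumulus and granulosa score (0.759, from few tested genes that include Cyp11a1) and the lowest second component (-52.7) of the 24 arrays. The 3 highest arrays lay in 3 different combinations of slide and row, which argues against a slide position as the source. An embryo left at an early cleavage stage in the pool remains a candidate source: oocyte and maternal transcripts had a median deviation of -0.05 log2 in HC6 replicate 3, inside the range of the other arrays, and 8 of 20 such genes were well above background there, but a 2-cell embryo that has lost its maternal RNA would give this too, and no profile of such an embryo was used here. Whether the condition HC6 plays a part cannot be told apart from differences between pools, since the exact test of the score had p = 0.0136 and an adjusted p of 0.989.

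Cholesterol synthesis genes were higher in HC5 with the preset correlation. With array position as a block the median was 0.181 (0.214 without the block), which argues against position as the whole source of the difference. The adjusted p of that camera fit was 2.11e-05, but it used the preset correlation and does not allow for shared variation. The list's genes vary together from pool to pool (estimated correlation 0.367), and with that correlation the adjusted p was 0.987, so shared variation between pools may account for the call. The condition HC5 stays open: the exact test of the score had p = 0.0168 and an adjusted p of 0.989, which does not exclude a difference.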

How the results depend on the processing

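Fits with slide row or array position, within rows, or without a pair of arrays were chosen after seeing the data, as were the regroupings of the arrays; the others were planned. The number of genes called by the F-test was 0, and 46 of 48 alternatives also gave 0. The exceptions were the fit within slide row 2, which held 1 HC4 pool, and the fit without HC1 replicate 3 (1 gene). HC3 gave 0 under all 48. For the other contrasts, most alternatives gave 0. No filter on dim probes gave 1 in HC5; within slide 1 there were 4 in HC5 and 3 in HC6; array weights gave 1 in HC4 (Fam167b); the Y-linked covariate gave 1 in HC6; within slide row 1 there were 3 in HC2; within slide row 2 there were 1 in HC1, 16 in HC4 and 26 in the pairs. Leaving out each array gave 0 to 1 by the F-test and in HC1 (1 without HC1 replicate 3), 0 to 4 in HC2 (4 without HC2 replicate 1), 0 to 2 in HC4 (2 without HC4 replicate 4), 0 to 1 in HC5 (1 without HC5 replicate 1), 0 in HC3 and HC6, and 0 to 4 in the pairs (4 without HC1 replicate 3, 3 without HC4 replicate 4). The count of list calls was 8. It was 0 with the estimated correlation and 0 with fry, 34 without a filter on dim probes, 3 with only probes well above background on all arrays (where the 2-cell list has too few genes), 15 with array weights, 18 within slide row 1 and 5 within slide row 2, and 6 to 12 when leaving out each array. The other alternatives stayed within 1.5 times. The cause of these moves was not tested. The list test with slide as a random block was not run, since camera takes no random block; the correlation within slides was -0.0297. Directions turned for Wnk4 in HC3 after normexp and quantile normalization (-0.126), where another probe of the gene may have been taken. They turned for Irx3os in HC1 within slide 2 (-0.155) and Fam167b in HC4 within slide row 2 (-0.415). Heat shock in HC2 turned within slide 3 (0.0351). Each of these 3 fits held 1 pool of the condition. Primitive endoderm in HC1 turned within slide 1 (-0.166) and cholesterol synthesis in HC3 within slide row 2 (0.0234). The median alone, and not the test, turned for 2-cell stage genes in HC2 within slide 2 (-0.764) and heat shock in HC2 within slide 1 (0.0464). The cholesterol shift in HC5 passed in 46 of 48 alternatives, all of them with the preset correlation of 0.01. The estimated correlation of this list was 0.367, so these passes are not independent support. Some of those fits also held 1 HC5 pool. The shift failed with the settings that allow for correlation between genes: camera with the estimated correlation (adjusted p = 0.987) and fry (adjusted p = 0.97).

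Same-numbered pools of different conditions showed no clear shared deviation. Their mean correlation was 0.017, against -0.00433 for pools that differed in condition and number. Of 60 same-numbered pairs, 25 had a correlation over 0.1 (range -0.324 to 0.338), and 7 of 24 arrays correlated best with their own number. The numbers were therefore not taken to pair the samples. These deviations still held the array position effect, so pairing is not excluded. With the replicate block the F-test, the 6 contrasts and the pairs gave 0 and the lists 8, and with slide row added 0 and 8. At least 8 list calls came in 58 of 100 regroupings of the 24 arrays, the real one included. All 99 other regroupings gave list calls, with a median of 9 and a highest of 17. The real count of 8 is thus no larger than random regrouping commonly gives, and chance cannot be excluded for it. The regroupings were drawn freely over slide rows and positions. For the real counts of 0 the comparison is void, since all 100 regroupings give at least 0. The highest other count was 229 by the F-test, 3 in HC1, 7 in HC2, 3 in HC3, 544 in HC4, 8 in HC5, 329 in HC6 and 14 in the pairs. The counts of 229, 329 and 544 may reflect a structure of the arrays other than condition, and which one was not tested. Signal over background limits the receptor genes: Esr1 and Gper1 were not tested.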

Other observations

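Genes of other cell types were tested in part. Over all probes, 27144 of 56605 passed the background filter. Of 18 cumulus and granulosa genes on the array 5 were tested, and of 12 oviduct and uterine epithelium genes 6, of which 3 were well above background on all 24 arrays. Of 20 oocyte and maternal genes 9 were tested, of 12 blood and immune genes 6, and of 12 sperm and testis genes 5. The oxidative phosphorylation genes were the opposite, with 24 of 24 tested and well above background on all arrays. Primitive endoderm genes moved together between pools of one condition: their score was -0.64 in HC5 replicate 3 and 0.40 in HC5 replicate 1, and the estimated correlation among list members was 0.358.

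HC6 replicate 3 held other unusual levels, chosen after they were seen. Zscan4c stood at 3.15 and Tcstv1 at -0.46 in normalized log2 signal, both well above background, as they were on 2 and 1 of the 23 other arrays, while Zscan4d was not well above background on any array. Cyp11a1, the first enzyme of steroid synthesis, stood 2.73 log2 above the median of the others. Il6, an interleukin gene well above background on the other 23 arrays, was not well above background here.

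One hypothesis, tested after the values had been seen, was that pools differ in their share of male embryos, which could give opposite moves of Xist and the Y-linked genes. Xist and the mean of the 4 Y-linked genes had Pearson r = -0.356 over 24 pools (permutation p = 0.088) and Spearman rho = -0.319 (permutation p = 0.129), with no other relation of this kind computed. Without the 2 pools farthest in Xist r was -0.289 (permutation p = 0.191). It was -0.70 within slide 1, -0.378 within slide 2, 0.143 within slide 3, -0.726 within slide row 1 and 0.0592 within slide row 2. The probes used for Ddx3y, Uty and Kdm5d were well above background on 16, 17 and 19 of 24 arrays, and that for Eif2s3y on all 24. The mean of the 4 genes thus holds background signals and is a blunt measure of male share. Array position was not taken out of these values. The relation did not pass the threshold and did not hold within every slide or row, so the data leave the hypothesis open.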
